A study of Mus musculus with 58 samples.

How the data were processed

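RNA of liver (31 samples) and soleus muscle (27 samples) from 4 groups of mice was labelled with Cy3 from 200 ng of total RNA per the labels and hybridised to 58 single-colour Agilent arrays of 1 design on 9 slides. The scanner files deposited by the authors give, per the file headers, spot intensity from Agilent Feature Extraction 12.0.3.1, and the processed signal used here is an intensity after background subtraction and detrending by the scanner software, with no scaling between arrays. The value table deposited by the authors holds a score, the Z-score of the log signal of each array. Recomputing that score from the scanner files gave r of at least 0.999996 per array and differences of at most 0.005, with column medians from −0.63 to −0.14. Each array has 62976 features, of which 59305 are spots of 55681 probes and 3671 are controls, and control spots and spots called outliers by the scanner software were left out. No spot was saturated (0 spots), 0 columns of the value table were left unmapped, and 0 pairs of arrays were identical, the highest correlation between arrays being 0.984.

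Probes were named through their RefSeq accessions with a table of assembly GRCm38.p6, while the array grid was annotated on another build, so no coordinates are given. A name was found for 28331 probes, giving 21368 genes, of which 5754 had over 1 probe, and 27350 probes without a name were left out. Signals were put on the log2 scale and the 75th percentile of each array was subtracted. A probe entered where it was well above background, by the call of the scanner software, on at least 75% of the arrays of 1 group of the tissue and had at least 3 values in each group. The probe with the highest mean stood for its gene. The 75th percentile of the signal ranged from 174.13 to 3015.9 over liver arrays and from 518.72 to 1464.6 over soleus arrays, and the number of arrays limits the precision.

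Each tissue was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the package data.table (version 1.17.8) for reading and matplotlib 3.10.9 for figures. Groups came from the labels, and each replicate was taken as a separate sample, since nothing in the labels pairs replicates or says which liver and soleus arrays share a mouse. The comparisons were each treatment minus CTRL, EX_AF minus AF, EX_AF minus EX, and the interaction. Differences between tissues were fitted on both tissues together. P values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Of 44 hand-written lists (30 of functions and 14 of cell type or ribosomal markers), 614 of 622 genes were on the array. Lists with at least 5 genes tested were compared with the other genes by camera with a preset correlation of 0.01, missing values being filled with the group mean, and again with an estimated correlation.

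Genes were named by a rule. For each treatment minus CTRL it took the 5 largest rises, the 5 largest falls and up to 2 members per function list with the smallest adjusted p, and for the other comparisons the 3 largest rises and the 3 largest falls, among genes past the threshold. The largest changes were taken among symbols that are not names of clones, accessions, coordinates or predicted genes. Some genes that the rule picked are not reported here, and counts of picked genes and of list members include them. Groups, comparisons, lists, the rule and most alternatives were chosen before the data were examined. For a gene not well above background in any array of its dim group, the bound on its fold was the mean of the bright group minus the mean, over the dim group, of the higher of its own value and the dimmest spot called well above background on that array.

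The code was tested on simulated data with the spread of these arrays, drawn independently for each gene and without an effect of slide. At changes of 1.5-fold, 2-fold and 4-fold it found 38.8%, 76.1% and 93.9% of changed genes for liver AF minus CTRL and 17.9%, 61.2% and 86.4% for the liver interaction (14618 genes). For soleus it found 32.8%, 71.6% and 98.5% for AF minus CTRL and 11.9%, 38.8% and 80.3% for the interaction (14948 genes). Principal components and pairs of probes used probes well above background on at least 90% of the arrays of the tissue, and the intervals of pairs came from 1000 bootstrap draws. The bright corner signal of an array is the median of 14 control spots.

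The alternatives were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, a filter on every array, a minimum of 1.5-fold, eBayes with trend and robust estimation, a fit of only the groups compared, slide as a random or fixed block, a comparison within 1 slide, the liver AF arrays of the later scan series left out, the replicate number as a block, the value table of the series, all probes tested, camera with an estimated correlation, and each array left out in turn. Normexp was applied to the median signal of spots, a choice made after the files were seen because they hold no column of mean signal, and keeping the outlier spots was also added then. Intervals over arrays took the mean of a gene list on each array and the spread between arrays of a group, resampling arrays within groups for ratios, and were added after the results were seen.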

Results

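Liver and soleus muscle of 6-month-old male C57BL/6J mice were profiled on 58 Agilent single-colour arrays, 31 of liver and 27 of soleus. The 4 groups were sedentary mice fed ad libitum (CTRL), sedentary mice on alternate-day fasting (AF), mice that ran daily on a treadmill and were fed ad libitum (EX), and running mice on alternate-day fasting (EX_AF). In that order, liver had 7, 8, 8 and 8 arrays and soleus had 7, 8, 7 and 5. Per the labels, AF and EX_AF mice were killed on a fasting day and EX mice 18 h after their last session, and the labels give no such interval for EX_AF mice. Comparisons of AF or EX_AF with mice fed ad libitum therefore cannot tell the regimen from the fasted state at death. The training time is 4 weeks in one label and 8 weeks in another. Changes are log2 differences between group means with their standard errors (SE) from limma, and a gene is said to rise or fall where its adjusted p was under 0.05 over all genes tested in its tissue. The number of arrays per group limits the precision of every value. EX_AF of both tissues and EX of soleus each filled 1 slide alone, the other groups shared a slide or lay on several, and counts of genes with slide as a random block are given beside the comparisons. For a group alone on its slide this block cannot separate slide from group. In soleus its correlation within slides was negative (−0.0432), which shrinks standard errors. The larger soleus counts with this block are therefore no evidence that slide did not matter.

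In liver of sedentary mice, alternate-day fasting (AF minus CTRL) lowered genes of fat and sterol synthesis and raised genes of fatty acid oxidation. Fasn, the fatty acid synthase, went from 3.40 ± 0.67 in CTRL to −0.20 ± 0.60 in AF (mean ± SD, log2 signal relative to the array's 75th percentile, 7 and 8 arrays), a change of −3.59 ± 0.28 (SE, adjusted p = 4.8e-10). Thrsp, which promotes lipogenesis, changed by −3.14 ± 0.25, and Fdps and Mvd of the mevalonate pathway by −2.37 ± 0.15 and −2.07 ± 0.21. Cyp4a10 and Cyp4a31, fatty acid omega-hydroxylases under the nuclear receptor PPAR-alpha, were 8.25-fold and 8.10-fold higher with fasting. Hadha and Eci2 of mitochondrial beta-oxidation rose 1.68-fold and 2.32-fold, but neither passed with slide as a fixed block or without the later scan series.

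Of the 18 mitochondrial fatty acid oxidation genes tested in that comparison, 18 rose (18 adjusted over the list alone), and of the 22 PPAR-alpha targets, 16 rose and 6 did not pass (17 adjusted over the list alone). The 16 genes of de novo lipogenesis had 11 that fell and 5 that did not pass, and the 24 of cholesterol synthesis 19 and 5 (11 and 19 adjusted over the list alone). Against the other genes, camera with its preset correlation gave adjusted p = 3.4e-10 for fatty acid oxidation, 6.5e-10 for the PPAR-alpha targets, 2.2e-10 for lipogenesis and 4.6e-15 for cholesterol synthesis. None of these 4 calls held with an estimated correlation, which gave adjusted p = 0.23, 0.087, 0.087 and 0.087.

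Genes that differ between male and female liver moved as well. Cux2, a female-biased transcription factor, was at least 7.63-fold higher with fasting. Such bounds are given where a group had no array with the probe well above background, whose value was then set no lower than the dimmest spot above background on each array. Of the 10 female-biased genes tested, 9 rose and 1 did not pass (9 adjusted over the list alone), with adjusted p = 2.6e-06 by camera and 0.039 with an estimated correlation. Of the 14 male-biased genes, 5 fell, 1 rose and 8 did not pass (5 and 1 adjusted over the list alone), with adjusted p = 0.0045 by camera and adjusted p = 0.59 with an estimated correlation. The male-biased steroid dehydrogenase Hsd3b5 was 10.6-fold lower, a change of −3.40 that became −2.82 with slide as a random block (adjusted p = 0.10) and −1.998 with slide as a fixed block (adjusted p = 0.67), and the male-biased genes Nudt7 and Serpina4-ps1 changed by −1.55 and −3.15. Among other genes with large changes, Cyp2b9 (8.91-fold) and the transporter Slc6a21 (8.64-fold) rose, while the fatty acid binding protein Fabp5 (11.8-fold), the receptor subunit Chrna4 (11.4-fold) and Moxd1 (at least 5.53-fold) fell. Moxd1 stood at −3.54 with slide as a random block (adjusted p = 0.059) and at −2.25 with slide as a fixed block (adjusted p = 0.65), where Cux2 (3.29, adjusted p = 0.090), Cyp2b9 (adjusted p = 0.13), Chrna4 (−3.68, adjusted p = 0.057) and Serpina4-ps1 (−2.84, adjusted p = 0.24) did not pass either. For Moxd1 and Cux2 these log2 values rest on a group not well above background, so their sizes are not exact.

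Other genes were picked as members of function lists, most of which were not called as a whole. The glycolytic enzyme Pklr changed by −1.69 ± 0.17 and Pfkfb1 by −0.75, the pyruvate carboxylase Pcx by 0.54 and the alanine aminotransferase Gpt by 0.53. The clock genes Hlf and Per1 changed by 1.06 and 1.13, Igfbp2 and Igfals, which bind insulin-like growth factors, by 1.23 and 0.66, and the chaperone genes Sdf2l1 and Calr by −1.21 and −0.81. Bnip3 and Atg2a of autophagy changed by 1.06 and 0.47, Abcg5 and Slco1a1 of sterol and bile acid transport by 0.68 and −1.02, and the acute-phase genes Itih3 and Steap4 by 0.57 and −0.98. Pgd and Gpx1 of redox balance changed by −0.998 and 0.71, Mcm7 and Mcm2 of replication by 0.50 and −1.07, the early-response genes Gadd45b and Egr1 by 1.42 and −2.75, and the interferon-induced Ifih1 and Ifi44 by −0.66 and −0.86. The respiratory genes Cox4i1 and Sdhb changed by 0.48 and 0.58, Idh2 of the citric acid cycle by 0.79, and Esrra and Polrmt of mitochondrial biogenesis by 0.70 and 0.42. Cox4i1, Sdhb, Gpx1, Itih3, Pcx and Gpt did not pass after quantile normalization. With slide as a random block Pklr, Hlf, Igfbp2, Sdf2l1, Calr, Pgd, Egr1 and Esrra passed, and the other genes given with them, from Bnip3 (adjusted p = 0.056) to Slco1a1 (adjusted p = 0.44), did not.

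Further lists called by camera in this comparison were autophagy and lysosome (10 of 20 rose, 10 not passing), oxidative phosphorylation (13 of 28 rose, 15 not passing, 16 adjusted over the list alone), the citric acid cycle (9 of 14 rose, 5 not passing) and regulators of mitochondrial biogenesis (4 of 12 rose, 8 not passing). The unfolded protein response had 6 of 17 that fell, 1 that rose and 10 not passing, and the interferon response 3 of 16 that fell and 13 not passing (1 adjusted over the list alone). Their adjusted p values were 0.0045, 0.0043, 0.020, 0.0496, 0.037 and 0.033, and at least 0.59 with an estimated correlation. With quantile normalization the first 4 of these calls ended. No call was made for ketone body metabolism (5 rose, 1 fell, 2 not passing), gluconeogenesis (7 of 20 rose, 13 not passing), glycolysis (2 rose, 3 fell, 9 not passing, with a median change of 0.14 and a mean of −0.07), bile acid synthesis (2 rose, 2 fell, 6 not passing), the growth hormone axis (5 of 12 rose, 7 not passing), the circadian clock (4 rose, 2 fell, 12 not passing), the acute phase (4 rose, 1 fell, 16 not passing), antioxidant genes (7 rose, 4 fell, 6 not passing), the cell cycle (3 rose, 3 fell, 11 not passing), immediate early genes (2 rose, 2 fell, 12 not passing) or extracellular matrix (15 not passing).

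Beside these, ribosomal protein genes had 14 of 23 that rose and 9 not passing (20 adjusted over the list alone; adjusted p = 5.2e-04 by camera, adjusted p = 0.59 with an estimated correlation, and no call after quantile normalization). Adipocyte markers had 3 of 6 that fell and 3 not passing (adjusted p = 0.018 by camera, adjusted p = 0.48 with an estimated correlation). Markers of hepatocytes (2 of 8 rose, 6 not passing), macrophages (12 not passing), endothelium (2 of 10 rose, 8 not passing), stellate cells and fibroblasts (2 rose, 1 fell, 5 not passing), cholangiocytes (6 not passing), pancreatic acinar cells (1 rose, 2 fell, 3 not passing), erythroid cells (1 of 6 fell, 5 not passing), lymphocytes (1 of 9 fell, 8 not passing) and neutrophils (5 not passing) were not called. In all, 5512 of 15596 genes changed with fasting in sedentary mice, 3237 up and 2275 down, and among those changed at least 1.5-fold 1075 rose and 1895 fell. The balance of rises and falls depended on the processing. Without a minimum fold, 3260 rose and 741 fell among 10418 genes with probes well above background on every array. With normexp it was 1867 and 668, and with quantile normalization 2506 and 2236.

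The AF arrays of liver lay on 3 slides, 6 of the 8 on a slide scanned in a later series, and fewer genes passed when slide was fitted. With slide as a random block 447 genes changed, and with slide as a fixed block 240. The single AF array on the slide of the 7 CTRL arrays, on which the fixed block rests too and which is assumed to vary like the other groups, gave 447, and the 2 AF arrays outside the later scan series, of which it is 1, gave 251. This array, AF replicate 1, had a median of 46.7 in its negative control spots, against 3.39 to 8.03 on the other sedentary liver arrays, and 33.2% of its probes well above background, the lowest share in liver. Without it 6245 genes changed. Of the 50 genes that the naming rule picked, 24 passed with the random block and 13 with the fixed block. Fasn, Thrsp, Fdps, Mvd, Cyp4a10, Cyp4a31, Fabp5, Slc6a21, Nudt7 and Sdf2l1 passed with the random block, the fixed block and without the later scan series, and all of them but Slc6a21, which was not tested there, within 1 slide. Hadha and Eci2 did not pass with the fixed block (0.59 and 0.90, adjusted p = 0.13 and 0.24). Without the later scan series they stood at 0.55 and 0.79 (adjusted p = 0.080 and 0.15). Slc16a1, a carrier of ketone bodies and lactate, fell by 1.08 over all arrays but stood at 0.01 with the fixed block. The calls for fatty acid oxidation, PPAR-alpha targets, lipogenesis, cholesterol synthesis and female-biased genes held with the random block, though with an estimated correlation only that for female-biased genes did.

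In liver of running mice (EX_AF minus EX), fasting again lowered genes of fat and sterol synthesis. Fasn changed by −3.97 ± 0.27 (15.7-fold, adjusted p = 1.8e-11, 8 arrays per group) and Fabp5 by −4.13 ± 0.28 (17.5-fold), while Moxd1 was 30.7-fold lower. Cux2 rose by 4.64 ± 0.43 (24.9-fold) and Slc6a21 by 2.74 ± 0.28 (6.66-fold). Of the 16 lipogenesis genes, 13 fell and 3 did not pass (14 adjusted over the list alone), and of the 24 cholesterol synthesis genes, 22 fell and 2 did not pass (22 adjusted over the list alone). Camera gave adjusted p = 1.9e-19 and 3.2e-26, and 0.014 for each with an estimated correlation. Female-biased genes had 3 of 10 that rose and 7 not passing (4 adjusted over the list alone; adjusted p = 1.2e-04 by camera, 0.044 with an estimated correlation).

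The PPAR-alpha targets had 8 of 22 that rose, 1 that fell and 13 not passing in running mice (10 and 1 adjusted over the list alone; adjusted p = 0.0031 by camera, adjusted p = 0.72 with an estimated correlation). Mitochondrial fatty acid oxidation had 3 of 18 that rose and 15 not passing (adjusted p = 0.14). Camera also called the unfolded protein response (7 fell, 1 rose, 9 not passing), male-biased genes (3 of 14 fell, 11 not passing), glycolysis (3 of 14 fell, 11 not passing), regulators of mitochondrial biogenesis (3 of 12 rose, 9 not passing) and ribosomal protein genes (23 not passing), none with an estimated correlation (adjusted p = 0.56, 0.72, 0.72, 0.72 and 0.87 with an estimated correlation). The last 3 calls ended with quantile normalization. Over all genes 2835 changed, 1135 up and 1700 down, and 120 with slide as a random block. On the value table of the series 1795 changed, 900 up and 895 down.

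Across the 15596 genes, the fasting changes with and without running, which share no arrays, had Pearson's r of 0.41, and 59.8% of genes had the same direction, a description over genes that are not independent replicates. The genes that rose in both numbered 617, against 235.57 for independent lists, those that fell in both 524 against 247.98, and 52 changed in opposite directions. The interaction, (EX_AF minus EX) minus (AF minus CTRL), tested whether the fasting effect differed. Cyp4a10 had an interaction of −2.39 ± 0.33 (adjusted p = 3.0e-04), rising by 3.04 in sedentary and by 0.66 in running mice. Acot3, a peroxisomal acyl-CoA thioesterase, had −2.40 ± 0.40 (adjusted p = 0.0044), and Rgs8, a regulator of G-protein signalling, −2.33 ± 0.67 (adjusted p = 0.029). Olfr100, Tmem72 and Tas2r118, an olfactory receptor, a membrane protein and a taste receptor, had interactions of 3.33, 3.21 and 3.12, and did not pass with normexp background correction. None of these 6 genes passed with slide as a random block (adjusted p = 0.99) or without the later scan series, where Tmem72 turned to −0.20 (adjusted p = 0.99).

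In the interaction, 12 of 18 fatty acid oxidation genes were lower and 6 did not pass (15 adjusted over the list alone), as were 8 of 22 PPAR-alpha targets with 14 not passing (14 adjusted over the list alone). Camera gave adjusted p = 2.2e-06 and 6.1e-05 (adjusted p = 0.84 with an estimated correlation for each). Oxidative phosphorylation (8 of 28 lower, 20 not passing), the citric acid cycle (7 of 14 lower, 7 not passing) and autophagy (4 of 20 lower, 16 not passing) were called beside ribosomal protein genes (15 of 23 lower, 8 not passing), hepatocyte markers (8 not passing, 7 lower adjusted over the list alone) and adipocyte markers (1 of 6 higher, 5 not passing). Their adjusted p was 0.84 with an estimated correlation. None of these 8 calls passed after quantile normalization, where fatty acid oxidation had adjusted p = 0.069 and the PPAR-alpha targets 0.0504. The interaction held for 1740 genes, 403 higher and 1337 lower, for 801 after quantile normalization (356 higher, 445 lower), for 3 without the later scan series, and for 0 of the genes fitted by limma with slide as a random block.

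**Figure D1:**
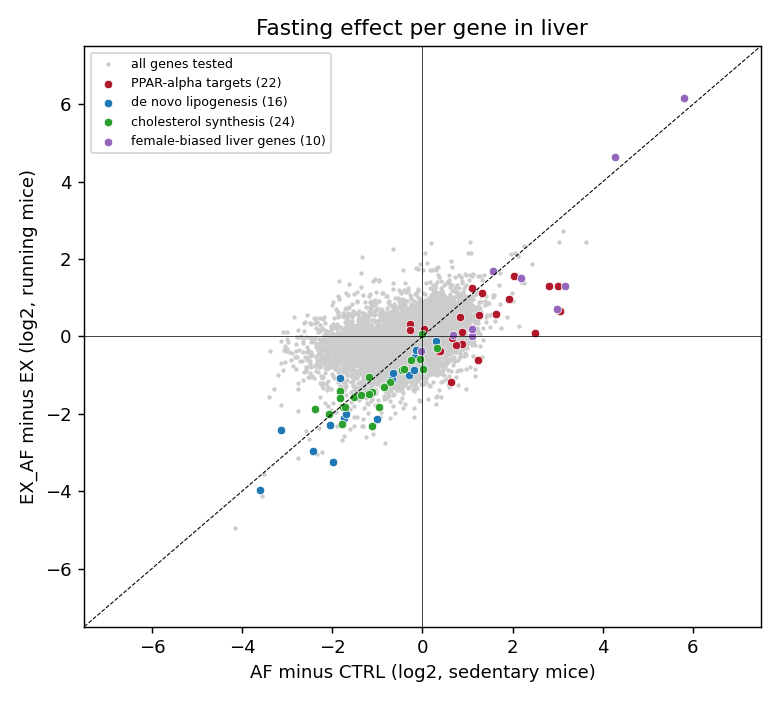
Each point is 1 gene in liver, with the log2 change with fasting in sedentary mice (AF minus CTRL) on the horizontal axis and in running mice (EX_AF minus EX) on the vertical axis, and 4 gene lists are coloured. Across genes r was 0.41, and cholesterol synthesis genes lie below 0 on both axes in most cases (19 of 24 fell in sedentary and 22 of 24 in running mice).

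Liver arrays of running mice differed from those of sedentary mice in how they were read out as well as in the genes called. The bright corner spots, control spots of the array, read 14738 to 102440 on the 15 sedentary arrays and 322980 to 613240 on the 16 running arrays. Spots called outliers numbered 85 to 178 and 458 to 1924 per array, and the 75th percentile of the signal was 174.13 to 824.7 and 859.84 to 3015.9. In soleus the bright corner spots read 140730 to 369440 on sedentary and 226180 to 562450 on running arrays. Every soleus array thus lay above the sedentary liver arrays in that signal. On the first principal component of liver, which took 69.9% of the variance, the sedentary arrays lay between −89.5 and −66.3 and the running arrays between 57.4 and 87.0. The comparisons across that divide called 11634 of 15596 genes for running with free feeding (EX minus CTRL; 6589 up, 5045 down), 11926 for both interventions together (EX_AF minus CTRL; 6429 up, 5497 down) and 11883 for running with fasting (EX_AF minus AF; 6084 up, 5799 down). With slide as a random block they called 9044, 9005 and 9178. After quantile normalization more genes fell than rose, with 5518 up and 5714 down, 5493 up and 6143 down, and 5290 up and 6313 down in that order, as on the value table of the series (5230 and 5522, 5350 and 5772, 5134 and 6116).

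The probes for a gene often moved apart in those comparisons. Across 2846 genes, a random pair of probes per gene had r = 0.0667 for EX minus CTRL, 0.126 for EX_AF minus CTRL and 0.121 for EX_AF minus AF, and the brightest pair 0.184, 0.217 and 0.181. The fasting comparisons had 0.514 (AF minus CTRL) and 0.520 (EX_AF minus EX) for random pairs, and 0.543 and 0.535 for the brightest. Of the genes with over 1 probe and any call, 32.1% had probes called in both directions in EX minus CTRL and 3.05% in AF minus CTRL. Each gene-level value below comes from 1 probe.

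**Figure D2:**
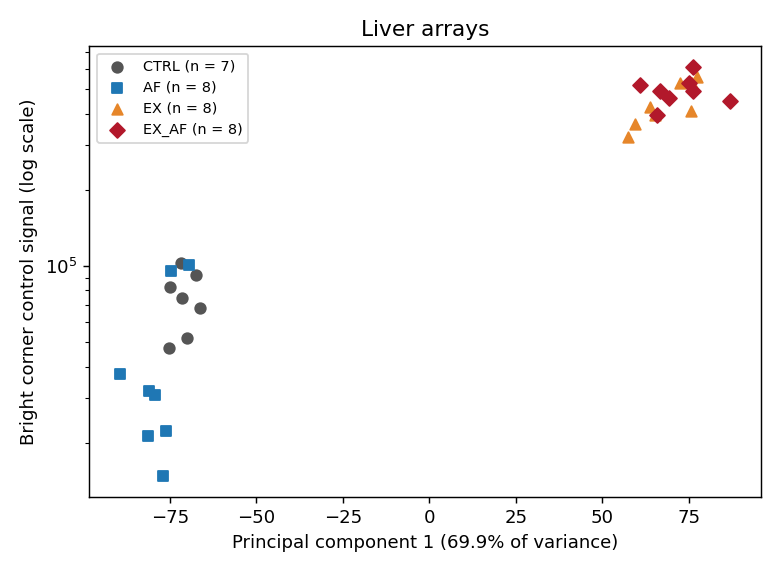
Each point is 1 liver array, with the median signal of its bright corner control spots on a log axis and its score on principal component 1, which took 69.9% of the variance. The 15 sedentary arrays (CTRL and AF) and the 16 running arrays (EX and EX_AF) do not overlap on either axis.

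With running and free feeding (EX minus CTRL), Slc16a1, the lactate and ketone body carrier, rose by 6.92 ± 0.23 (adjusted p = 7.4e-21, 7 arrays with values per group), Acat1 by 1.56 and the glucose-6-phosphate carrier Slc37a4 by 1.75. Hadha and Acads of fatty acid oxidation changed by −2.09 ± 0.10 and −2.04 ± 0.13, the uncoupling protein Ucp2 by −1.63 and the thioesterase Acot4 by 1.03. The clock genes Cry2 and Nr1d1 changed by 3.66 ± 0.17 and −2.72 ± 0.16, the autophagy genes Ulk1 and Map1lc3b by 2.93 and 1.44, and the growth hormone axis genes Igf1 and Stat5b by 1.63 and 1.42. Among the largest rises were Lca5 (11.39), Mmel1 (at least 273-fold), Camk2a (9.92) and A3galt2 (8.99), and the largest falls were Vmn1r217 (at least 23.0-fold), Cfap73 (at least 17.8-fold), Trim43c (41.5-fold), Rasgrf2 (at least 10.99-fold) and Sult4a1 (at least 15.4-fold). Another probe for Lca5, Camk2a, Mlxipl, Hsd17b7, Fga, Sdhc, Ogdh and Igf1 was called in the opposite direction. Camk2a rested on 3 EX arrays with a value.

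Other genes named by the rule in that comparison moved both ways. Ogdh and Dlst of the citric acid cycle changed by 2.45 and −2.13, the respiratory genes Ndufb5 and Sdhc by 2.27 and 2.13, and Tfb2m and Esrra of mitochondrial biogenesis by 1.82 and 1.34. Otc of the urea cycle changed by 1.71, Mlxipl and Pfkl of glycolysis by 1.76 and −1.13, Slc25a1 and Fads2 of lipid synthesis by −1.56 and −1.33, and Hsd17b7 of the cholesterol pathway by 1.35. Abcb11 and Cyp7b1 of bile acid handling changed by 1.58 and 2.02, the male-biased Nudt7 by 1.07, the female-biased Cyp3a16 by 1.07 and Cyp2b9 by at least 3.41-fold downward. Orm2 and Fga of the acute phase changed by −1.82 and 0.98, the chaperone genes Dnajc3 and Hsp90b1 by 1.59 and 1.06, Gclc and Taldo1 of redox balance by 1.53 and 1.10, and Tk1 and Mcm2 of replication by 1.06 and 1.55. The early-response genes Junb (at least 5.15-fold) and Ier2 (2.63-fold) fell, as did the interferon-induced Ifit2 (4.57-fold), while Ifih1 rose 2.03-fold. The matrix genes Bgn and Fbn1 changed by −1.9999 and 1.63. Cyp3a16, Fga, Hsp90b1, Taldo1 and Tk1 did not pass after quantile normalization. No list was called in this comparison (lowest adjusted p = 0.41).

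With both interventions (EX_AF minus CTRL), the lipogenesis list was the 1 list called, with 14 of 16 that fell and 2 not passing (14 fell and 1 rose adjusted over the list alone; adjusted p = 0.0016 by camera, adjusted p = 0.97 with an estimated correlation). Srebf1, the lipogenic transcription factor, changed by −2.61 ± 0.19 and the citrate carrier Slc25a1 by −2.42 ± 0.11. Mvd, Dhcr7 and Pklr changed by −2.39, −2.21 and −2.29, while Acadl of fatty acid oxidation changed by 2.66 ± 0.16 and the PPAR-alpha targets Acot1 and Acot4 by 2.45 and 2.16. Cux2 was at least 28.3-fold higher, and Nr1d1 changed by −4.11. The largest rises were again Lca5 (11.23), Mmel1 (at least 436-fold) and Camk2a (9.56), with Zbtb26 (9.12) and Ccdc169 (9.00). The largest falls were Vmn1r217 (75.6-fold), Olfr740 (at least 18.0-fold), Trim43c (at least 36.9-fold), Cfap73 (at least 20.1-fold) and Egr1 (49.5-fold). Others named by the rule were Cdk1 (2.96), Gclm (2.22), Ddit3 (−2.11), Ifi44 (−2.24), Sdf2l1 (−2.16), C3 (−1.26), Mup20 (−1.16), Postn (1.80) and Abcg5 (1.48). Probes for Cdk1, Stat5b, Igf1, Ogdh, Sdhc, Mlxipl, Lca5 and Camk2a were called in both directions.

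Running with fasting (EX_AF minus AF) had Lca5 (12.35), Camk2a (11.87) and Ccdc169 (10.54) as its largest rises and Olfr740 (at least 23.3-fold), Vmn1r217 (62.9-fold) and Trim43c (at least 32.3-fold) as its largest falls, and no list was called (lowest adjusted p = 0.24). Camk2a turned to −2.41 without EX replicate 1, 5 or 7, when another probe stood for it. The running changes with and without fasting had r = 0.92 across genes, and 87.5% had the same direction. Both comparisons cross the divide between the liver arrays, and a technical shift shared by them would raise this r too. Hepatocyte markers had 7 of 8 that fell and 1 that rose in each of the 3 comparisons, and erythroid markers 5 of 6, 6 of 6 and 5 of 6 that fell, in the order EX minus CTRL, EX_AF minus CTRL and EX_AF minus AF. Neither list passed by camera. Quantile normalization moved the median of all genes from 0.17 to −0.01 for EX minus CTRL, from 0.11 to −0.06 for EX_AF minus CTRL and from 0.03 to −0.11 for EX_AF minus AF. The slide as a fixed block left 4652 genes for EX minus CTRL, estimated through the slide that held 1 AF and 1 EX array. Of the 55 genes picked by the naming rule for EX minus CTRL, 38 passed with it and 17 did not.

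In soleus of sedentary mice, alternate-day fasting (AF minus CTRL) raised PPAR-alpha targets. Acot1, a cytosolic acyl-CoA thioesterase, went from 2.15 ± 0.45 to 5.63 ± 0.34 (mean ± SD, 7 and 8 arrays), a change of 3.48 ± 0.23 (11.1-fold, adjusted p = 3.2e-10). Its mitochondrial relative Acot2 rose 4.44-fold, Pdk4, which restrains pyruvate oxidation, rose by 2.01 ± 0.26 (4.02-fold, adjusted p = 3.2e-05), the peroxisomal enzyme Ehhadh by 1.36 ± 0.14 (2.57-fold) and the lipid droplet protein Plin5 by 1.31 ± 0.22 (2.48-fold). Unc93a (4.24-fold) and the transcription factors Isl2 (3.78-fold), Myc (1.996-fold) and Cebpd (1.87-fold) rose too, as did Mcm7 (0.48) and the ubiquitin ligase subunit Fbxo21 (0.52). Sqle of cholesterol synthesis changed by −1.02 and the endothelial receptor Kdr by −0.59, which did not pass after quantile normalization. The largest falls were Mirg (−2.24 ± 0.53), Fam166b (−2.21), Gsg1l (at least 1.61-fold), Rab11fip4os1 (−2.07) and Hecw2 (−2.02 ± 0.32), of which Hecw2 had values on 4 CTRL and 5 AF arrays and stood at 0.01, 0.02 and 0.10 without CTRL replicate 1, CTRL replicate 3 or AF replicate 6, when another probe stood for it.

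Of 17 PPAR-alpha targets tested in soleus, 8 rose with fasting and 9 did not pass (9 adjusted over the list alone), with adjusted p = 3.0e-14 by camera and 0.0012 with an estimated correlation. Of 19 muscle atrophy genes, 2 rose and 17 did not pass (11 adjusted over the list alone; adjusted p = 1.8e-11, and 0.036 with an estimated correlation). Of 17 genes of lipid uptake and storage, 4 rose and 13 did not pass (7 adjusted over the list alone; adjusted p = 3.0e-07, adjusted p = 0.069 with an estimated correlation). Camera further called fatty acid oxidation (18 not passing) and mitochondrial biogenesis (12 not passing) upward, fast fibre genes (12 not passing) upward, and extracellular matrix (18 not passing), the interferon response (16 not passing), cholesterol synthesis (2 of 22 fell, 20 not passing) and muscle glycolysis (21 not passing) downward, with adjusted p from 0.0061 to 0.046 and at least 0.58 with an estimated correlation. The call for fast fibres ended with normexp, quantile normalization and the random slide block, that for glycolysis with quantile normalization, and those for the interferon response, mitochondrial biogenesis and fatty acid oxidation with normexp. The other 12 function lists were not called. In all, 191 of 15726 genes changed, 92 up and 99 down. After quantile normalization 370 changed (238 up, 132 down), with slide as a random block 548, with slide as a fixed block 10, and the 1 AF array on the slide of the CTRL arrays gave 1. Acot1, Acot2, Unc93a and Ehhadh passed with the fixed block, where Pdk4 stood at 2.48 (adjusted p = 0.092).

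Running alone (EX minus CTRL) left no gene past the threshold in soleus. Limma called 0 of 15726 genes, with 915 at an unadjusted p under 0.05, and the other settings tried gave 0 to 29. In simulated data with these group sizes and spreads, 25.4% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 97.0% of those changed 4-fold were found. The simulated spread was independent between genes, without slide, and 126 genes were called there, which eases the adjusted threshold. The share found may be lower where few genes change on the real arrays. Acot1 stood at 2.15 ± 0.45 and 1.97 ± 0.37 (mean ± SD, 7 arrays each) and Pdk4 at 6.66 ± 0.65 and 6.61 ± 0.66. The muscle atrophy list was the 1 list called (19 not passing; adjusted p = 0.015 by camera, adjusted p = 0.99 with an estimated correlation).

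Both interventions together (EX_AF minus CTRL) raised PPAR-alpha targets and muscle atrophy genes in soleus. Acot1 rose by 3.53 ± 0.26 (11.6-fold, adjusted p = 4.0e-09, 5 against 7 arrays), Acot2 4.64-fold and Plin5 4.32-fold. Arrdc2, an arrestin-domain gene, rose 8.97-fold, Ddit4, an inhibitor of mTORC1, 7.68-fold, Cebpd 6.04-fold, the kinase gene Map3k6 5.16-fold, Fkbp5, a co-chaperone of the glucocorticoid receptor, 4.87-fold, and Gadd45g 4.43-fold. Cebpd went from 3.87 ± 0.46 to 6.47 ± 0.55 and Fkbp5 from 3.06 ± 0.30 to 5.34 ± 0.92 (mean ± SD). Smaller rises were those of Btg2 (1.56), Nfil3 (1.51), Plin4 (1.39), Per2 (1.30), Chac1 (1.28), Rrm2 (1.06), Eci2 (0.95), Gabarapl1 (0.91), Tfam (0.79), Dlst (0.70), Dnajb9 (0.66), Dld (0.63) and Mcm7 (0.43). Falls were those of Slamf8 (at least 2.60-fold), Olfr351 (−2.05), Pate9 (−1.94), Cst10 (−1.92), Agxt2 (−1.87), Sqle (−1.34), Aplnr (−0.98) and Kdr (−0.89). Agxt2, Chac1, Dld, Dlst, Dnajb9, Mcm7, Cst10, Slamf8 and Tfam did not pass after quantile normalization.

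The muscle atrophy list had 11 of 19 that rose and 8 not passing in that comparison (14 adjusted over the list alone; adjusted p = 7.8e-13 by camera, 0.039 with an estimated correlation). The PPAR-alpha targets had 8 of 17 that rose and 9 not passing (8 adjusted over the list alone; adjusted p = 1.8e-06, and 0.044 with an estimated correlation). Lipid uptake and storage (6 of 17 rose, 11 not passing) and immediate early genes (6 of 14 rose, 8 not passing) had adjusted p = 1.5e-05 and 2.5e-04 (adjusted p = 0.13 and 0.12 with an estimated correlation). Fatty acid oxidation (1 of 18 rose, 17 not passing), autophagy (1 of 20 rose, 19 not passing) and mitochondrial biogenesis (1 of 12 rose, 11 not passing) were called upward, and the interferon response (16 not passing) and angiogenesis (2 of 14 fell, 1 rose, 11 not passing) downward, with adjusted p of at most 0.035. These 5 gave adjusted p = 0.59, 0.59, 0.59, 0.59 and 0.14 with an estimated correlation, and the calls for autophagy, mitochondrial biogenesis and the interferon response ended with quantile normalization. In all, 741 genes changed, 613 up and 128 down, 307 without EX_AF replicate 2, and 1730 with slide as a random block, which shrinks standard errors in soleus.

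**Figure D3:**
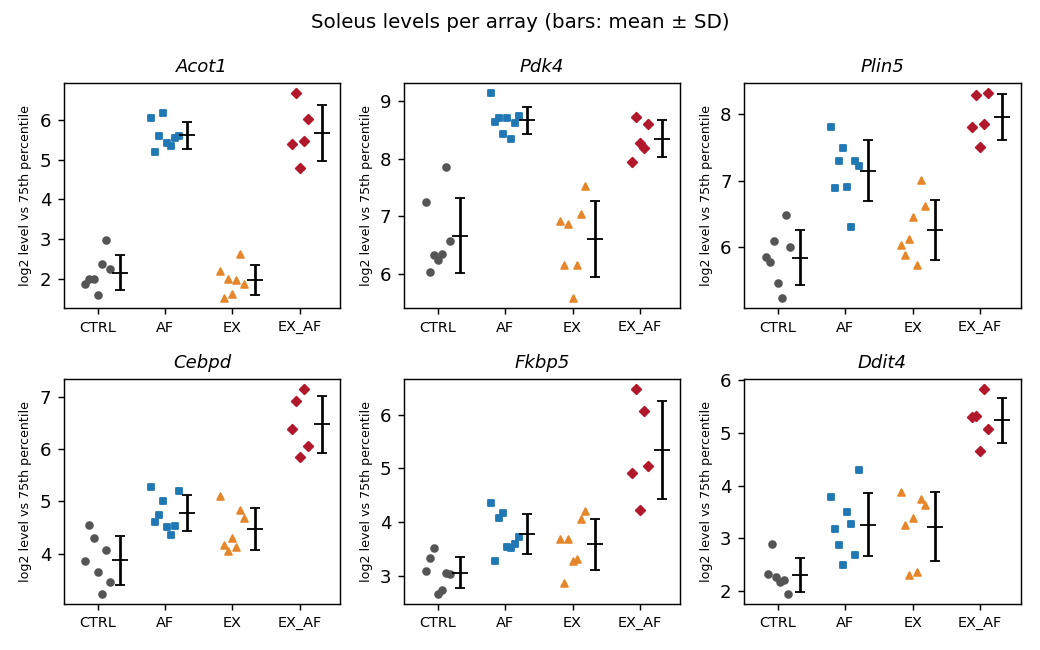
Each point is 1 soleus array, with the log2 signal relative to the array's 75th percentile for 6 genes in the 4 groups, and bars give the mean ± SD. Acot1 stood at 5.63 ± 0.34 in AF and 5.68 ± 0.72 in EX_AF, against 2.15 ± 0.45 in CTRL, while Cebpd stood at 6.47 ± 0.55 in EX_AF against 4.78 ± 0.34 in AF.

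Against fasting alone, the addition of running in soleus (EX_AF minus AF) raised Arrdc2 (2.38 ± 0.33, 5.19-fold, adjusted p = 2.7e-04), the kinase gene Sgk1 (2.02 ± 0.28, 4.05-fold) and Ddit4 (1.98 ± 0.29, 3.95-fold), and lowered Ankrd66 (−1.61), Lrrc55 (at least 1.96-fold) and Vmn1r68 (−1.41). Lrrc55 and Vmn1r68 did not pass after quantile normalization. Atrophy genes had 7 of 19 that rose and 12 not passing (8 adjusted over the list alone), and immediate early genes 5 of 14 that rose and 9 not passing (8 rose and 1 fell adjusted over the list alone). With fast fibre genes (12 not passing, downward) they were the 3 lists called (adjusted p = 0.010, 0.011 and 7.6e-04 by camera, adjusted p = 0.88, 0.70 and 0.70 with an estimated correlation), and the first call ended with quantile normalization. The clock genes had 6 of 17 that rose, 2 that fell and 9 not passing, without a call (adjusted p = 0.33). In all, 340 genes changed, 305 up and 35 down, with 94 to 1035 when single arrays were left out, 1598 with normexp and 2244 with slide as a random block. On component 1 of soleus, which took 19.9% of the variance, CTRL replicate 5 (−62.9) and AF replicate 6 (−66.7) lay below the other arrays (−37.8 to 43.3), and the count was 1035 without the former and 180 without the latter. After quantile normalization, which moved the median of all genes from 0.18 to 0.07, 104 changed (60 up, 44 down), and on the value table of the series 87 (50 up, 37 down).

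Fasting in running mice (EX_AF minus EX) also raised PPAR-alpha targets and muscle atrophy genes in soleus. Acot1 rose by 3.71 ± 0.26 (13.1-fold, adjusted p = 1.3e-09, 5 against 7 arrays), Acoxl, an acyl-CoA oxidase relative, by 2.29 ± 0.29 (4.89-fold) and Arrdc2 by 2.22 ± 0.34 (4.67-fold), while Kcng4 (−1.69), Nrip2 (−1.68) and Fasn (−1.67 ± 0.30) fell. Pdk4 rose by 1.74, Plin5 by 1.69, Cebpd by 1.998, Fkbp5 by 1.76 and Ddit4 by 2.02, these 5 being chosen after their values were seen. Atrophy genes (10 of 19 rose, 9 not passing, 13 adjusted over the list alone) and PPAR-alpha targets (7 of 17 rose, 10 not passing, 9 adjusted over the list alone) had adjusted p = 1.8e-11 and 4.4e-09 by camera, and 0.032 and 0.019 with an estimated correlation. Lipid uptake (5 of 17 rose, 12 not passing), immediate early genes (4 of 14 rose, 10 not passing), fatty acid oxidation (18 not passing) and mitochondrial biogenesis (12 not passing) were called upward and the interferon response (16 not passing) downward, with adjusted p = 0.21, 0.21, 0.59, 0.56 and 0.56 with an estimated correlation. In all, 351 genes changed, 329 up and 22 down, 152 without EX_AF replicate 2, and 1055 with slide as a random block. Kcng4 and Nrip2 did not pass after quantile normalization.

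Across the 15726 genes of soleus, fasting changes with and without running had r = 0.31, with 53.2% in the same direction. Genes that rose in both numbered 62 against 1.92 for independent lists, 7 fell in both against 0.14, and 0 changed in opposite directions (limma, adjusted p). The interaction held for 5 genes, each higher, among them Rbp7, a retinol binding protein (1.77 ± 0.29, adjusted p = 0.033), Tcim (1.45 ± 0.26, adjusted p = 0.049) and Csrnp1 (1.35 ± 0.26, adjusted p = 0.049). Gm3383 and Adgrg1 complete the 5 and are named after their values were seen. With quantile normalization limma called 0 genes, and with slide as a random block 11. The interaction for Acot1 was 0.24 ± 0.35 (adjusted p = 0.78) and that for Fkbp5 1.04 ± 0.39 (adjusted p = 0.48), which did not pass and were chosen after their values were seen. Fast fibre genes were the 1 list called (12 not passing, downward; adjusted p = 6.6e-04 by camera, adjusted p = 0.996 with an estimated correlation, and no call with normexp).

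Cell type markers in soleus were not called in any comparison. Markers of macrophages, endothelium, fibroblasts, adipocytes, erythroid cells, nerve, tendon and satellite cells and the ribosomal protein genes had at most 1 member that rose and 1 that fell in each comparison. Lymphocyte, neutrophil and hepatocyte markers had 3, 4 and 2 genes tested, too few for the list test. Among the function lists, slow fibre genes and the muscle stress and myokine genes had 0 members that passed in limma in any comparison.

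Whether the tissues differed was tested on 13900 genes as the soleus change minus the liver change. For AF minus CTRL the difference was 2.29 ± 0.21 for Fdps (adjusted p = 1.8e-11), 2.17 ± 0.40 for Fasn and 2.28 ± 0.39 for Pdk4. For Fdps and Fasn, which fell in liver, a positive difference is a larger fall in liver than in soleus. Pdk4, by contrast, rose in soleus. The difference was −3.61 ± 0.44 for Cyp4a10 and −4.50 ± 0.51 for Cux2, which rose in liver. The probe for Cux2 was not well above background on any liver CTRL array, so the size of its difference is not exact. Acot1 differed by 1.44 ± 0.33 (adjusted p = 0.0031) and Eci2 by −0.96 ± 0.27 (adjusted p = 0.013), while Hadha (−0.33, adjusted p = 0.21) and Acot2 (0.24, adjusted p = 0.69) did not pass. The genes of this paragraph were chosen after their values were seen. In all, 2075 genes differed for AF minus CTRL (598 higher in soleus, 1477 lower), 8455 for EX minus CTRL (3230 and 5225) and 8257 for EX_AF minus CTRL (3962 and 4295). With quantile normalization over all arrays, AF minus CTRL had 1513 (758 and 755), EX minus CTRL 8142 (3977 and 4165) and EX_AF minus CTRL 8395, now with more higher in soleus (4598) than lower (3797). With slide as a random block they had 83, 5868 and 5701. The comparisons of EX and of EX_AF with CTRL carry the liver array divide described above.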

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

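In a group of arrays, a value was listed where the gap between the highest or lowest array and its nearest neighbour, over the range of the group, exceeded Dixon's 95% limit, and that ratio is given for each. Of 650 groups of values of named genes, 46 were over the limit, where chance gives about 1 in 20 groups. Liver CTRL replicate 1 stood apart for 7 genes, liver EX_AF replicate 1 for 5 and soleus CTRL replicate 5 for 5. Among liver CTRL arrays it was replicate 1 for Gadd45b (0.643), Vmn1r217 (0.69), Hsd17b7 (0.582), Junb (0.583), Olfr740 (0.608), Acadl (0.706) and Ddit3 (0.65), replicate 4 for Rasgrf2 (0.608), Ulk1 (0.664) and Tmem72 (0.654), and replicate 6 for Cfap73 (0.615). Among liver AF arrays it was replicate 1 for Moxd1 (0.559) and Mmel1 (0.533), replicate 2 for Slc25a1 (0.671), replicate 3 for Polrmt (0.696), replicate 4 for Chrna4 (0.636), replicate 5 for Srebf1 (0.615), replicate 6 for Mup20 (0.554), and replicate 7 for Mcm2 (0.583). Among liver EX arrays it was replicate 2 for Hsd3b5 (0.532) and Acot3 (0.737), replicate 7 for Pcx (0.613), and replicate 8 for Gclc (0.554) and Tas2r118 (0.534). Among liver EX_AF arrays it was replicate 1 for Mcm2 (0.562), Egr1 (0.658), Ucp2 (0.528), Tk1 (0.648) and Ifit2 (0.671), replicate 2 for Junb (0.543), replicate 3 for Acot4 (0.703), and replicate 6 for Nr1d1 (0.533). Among soleus CTRL arrays it was replicate 1 for Unc93a (0.674), replicate 4 for Dnajb9 (0.584), and replicate 5 for Myc (0.583), Dlst (0.68), Dld (0.58), Aplnr (0.588) and Lrrc55 (0.647). Among soleus AF arrays it was replicate 3 for Tcim (0.553), replicate 6 for Plin4 (0.548), and replicate 7 for Btg2 (0.6). Among soleus EX arrays it was replicate 6 for Mcm7 (0.604) and Gabarapl1 (0.669), and replicate 7 for Rrm2 (0.619). Among soleus EX_AF arrays it was replicate 2 for Dld (0.73). The tests of a difference between groups gave 1740 genes whose fasting change differed with running in liver and 5 in soleus, and 2075, 8455 and 8257 genes whose change in AF, EX and EX_AF against CTRL differed between the tissues.

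Of the tests below, the later scan series of liver, the single array of soleus, the glucocorticoid signal and the splits for tissue differences, across-gene r and lists were written down before their result was seen, and the other tests, and all intervals over arrays, were chosen after it. Liver arrays of running mice stood apart from those of sedentary mice on component 1 and in control spots. In bright corner signal it was the sedentary liver arrays that lay below every soleus array. If running alone had caused this, probes of the same gene would change alike, but random pairs had r = 0.0667 for EX minus CTRL (95% interval 0.0288 to 0.105) against 0.514 for AF minus CTRL (0.464 to 0.562), so running as the whole cause is excluded. The slide as the whole cause is excluded too, on 1 pair of arrays, since the AF and EX arrays that share a slide lay 138.48 apart on component 1. A part from slide stays open, as EX minus CTRL had 4652 genes with slide as a fixed block, against 11634 without. Labelling or hybridisation that differed between the arrays may explain the divide. The lowest running array was 3.15 times the highest sedentary array in bright corner signal. That gap is part of the pattern itself and had been seen before, so it is no separate test of this explanation. Changes from running itself stay open beside this explanation, because no liver comparison of running with sedentary mice lies within 1 kind of array.

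PPAR-alpha targets rose less with fasting in liver of running mice, with a mean interaction of −0.86 (95% interval −1.22 to −0.51 over arrays), though the list call was lost with an estimated correlation (adjusted p = 0.84) and after quantile normalization (0.0504). A scale compressed by 1 factor for all genes on the running arrays is excluded, since the mean lipogenesis change was 1.28 times as large in running as in sedentary mice (0.973 to 1.64 over arrays) and the mean PPAR-alpha change 0.288 times (0.0821 to 0.494). Compression that varies with signal level was not tested by these ratios. After quantile normalization the interaction held for 801 genes, against 1740. With AF replicates 1 and 2 alone, outside the later scan series, the mean interaction was −0.57 (−1.04 to −0.10 over arrays, −0.89 to −0.24 over genes). An interval over genes below 0 was set beforehand as the outcome against that series. The values thus argue against it as the whole cause for these targets. They rest on 2 arrays, though: replicate 1 had a negative control median of 46.7, and replicate 2 alone (−0.65) has no spread of its own. A part from the series could not be excluded. Probe behaviour that differs between the kinds of arrays could not be excluded, the interaction having r = 0.296 for random pairs of probes, between the values of the fasting and the running comparisons, and with slide as a random block limma called 0 interaction genes. A smaller rise in fasted running mice stays a hypothesis.

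Targets of the glucocorticoid receptor, 20 genes listed by hand after 9 of them had been seen in soleus, were high in soleus of fasted running mice, with a mean EX_AF minus EX change of 1.18 (95% interval 0.839 to 1.51 over arrays). A single array as the cause is excluded, the lowest median without 1 EX_AF array being 0.989, while the slide cannot be told apart from the group, since the slide of these arrays held 1 group. A higher glucocorticoid signal in fasted running mice predicted a rise of the same targets in liver. There they had a mean EX_AF minus EX change of 0.785 (0.50 to 1.07 over arrays), with 11 of 20 higher, 0 lower by limma and camera p = 1.3e-10 (0.0023 with an estimated correlation). On the 11 targets not seen beforehand the liver mean was 0.46 (0.22 to 0.70 over arrays, and −0.04 to 0.97, which includes 0, over genes) and the soleus mean 0.81 (0.49 to 1.13 over arrays). All 20 also rose in the mean with fasting in liver of sedentary mice (0.54, 0.24 to 0.83 over arrays). Their mean liver interaction was 0.25 (−0.16 to 0.66). The liver rise therefore cannot tell such a signal from an effect of fasting, and it stays a candidate explanation. The liver EX_AF arrays also filled a slide alone, and the time from the last run to death of EX_AF mice is not given in the labels, which stays untested.

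Chance was tested by splitting the arrays in 100 ways, the real split included, on genes without missing values and with only the groups compared. For AF minus CTRL in liver 1 of the splits gave as many genes (real 6136, highest other 3350), for EX minus CTRL 1 (11159, 1), for EX_AF minus CTRL 1 (11131, 587), for EX_AF minus AF 1 (10680, 8152), and for EX_AF minus EX 1 (1852, 41). In soleus it was 1 for AF minus CTRL (125, 23), 1 for EX_AF minus CTRL (269, 3), 1 for EX_AF minus AF (809, 2), and 1 for EX_AF minus EX (370, 1), so chance is excluded for these where arrays exchange freely, while for EX minus CTRL it was 100 (0, 1). For the interaction, splits that exchange running labels gave 1 in liver (1714, 1) and 1 in soleus (5, 2), but in liver they mix arrays across the divide and so do not test the interaction alone. Residuals of a fit without the interaction were therefore exchanged between arrays, a test chosen after the results were seen, and 1 of 100 gave as many genes in liver (1714, highest other 32) and 2 of 100 in soleus (5, highest other 1246). In liver chance is excluded only where residuals exchange freely, and these too were exchanged across the divide. In soleus it is not called excluded, since 1 exchange gave 1246 genes, for a reason that was not tested. The 5 soleus genes also became 0 with quantile normalization. These tests take no account of slide, which follows the groups, and with slide as a random block the liver interaction had 0 genes by limma and EX_AF minus EX 120. For the tissue differences it was 1 for AF (2050, 1037), 1 for EX (7650, 5409) and 1 for EX_AF (7358, 18). The across-gene r of fasting was reached by 1 split in liver (0.45, 0.34) and by 2 in soleus (0.31, 0.32). As many list calls came from 58 splits in liver (30, 61) and 38 in soleus (29, 63). These splits mixed arrays of all groups, in liver across the divide, so real differences between groups entered them. They cannot tell whether chance gave the number of lists called with the preset correlation, and chance is not excluded for it.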

How the results depend on the processing

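Slide mattered most for liver. With slide as a random block, liver AF minus CTRL had 447 genes, EX_AF minus EX 120 and the interaction 0, and 145 of 177 calls of genes picked by the naming rule kept their side of the threshold in the same direction. With slide as a fixed block, AF minus CTRL had 240 and EX minus CTRL 4652, and Slc16a1 reversed to 0.0129. Within 1 slide AF minus CTRL had 447, with Slc16a1 at 0.0129, from 1 AF array that is assumed to vary like the other groups. Without the later scan series AF minus CTRL had 251 and the interaction 3, Slc16a1 stood at 0.0821 and Tmem72 reversed to −0.20 in the interaction, on fewer arrays. In soleus the random block, with a negative correlation within slides (−0.0432), gave 548 for AF minus CTRL, 29 for EX minus CTRL, 1730 for EX_AF minus CTRL, 2244 for EX_AF minus AF, 1055 for EX_AF minus EX and 11 for the interaction, the fixed block 10 for AF minus CTRL and the comparison within 1 slide 1. Tissue differences for AF minus CTRL had 83 genes with the random block. The consensus correlation within liver slides was 0.257.

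Scaling and background moved other counts, and the cause was not tested. Normexp gave 2535 for liver AF minus CTRL (1867 up, 668 down), 486 for the liver interaction and 1598 for soleus EX_AF minus AF. Quantile normalization gave 801 for the liver interaction, and in soleus 370 for AF minus CTRL, 104 for EX_AF minus AF and 0 for the interaction. The value table of the series gave 1795 for liver EX_AF minus EX and r = 0.30 for fasting across liver genes, with Igf1 at −0.00536 for EX_AF minus CTRL, and in soleus 401 for AF minus CTRL (304 up, 97 down), 432 for EX_AF minus CTRL, 87 for EX_AF minus AF, 166 for EX_AF minus EX and 0 for the interaction. It gave 1326 tissue differences for AF minus CTRL (714 higher in soleus, 612 lower). The liver interaction was 2324 there (918 higher, 1406 lower). Of the 66 calls of soleus genes picked by that rule, 47 kept their side with quantile normalization, 58 with normexp and 46 on the value table, and of the 177 in liver 166, 168 and 169.

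Filters, thresholds and models came next. Without a filter on dim probes the liver interaction had 1000 genes, and soleus had 189 for EX_AF minus AF, 229 for EX_AF minus EX and 0 for the interaction. Probes above background on every array gave 1 for soleus EX minus CTRL and 821 for EX_AF minus AF, on fewer genes. The minimum of 1.5-fold left 2970 for liver AF minus CTRL and 1408 for EX_AF minus EX, as it must remove smaller changes. Trend and robust estimation gave 1 for soleus EX minus CTRL and 635 for EX_AF minus AF, and only the groups compared gave 244 for EX_AF minus CTRL and 816 for EX_AF minus AF. Outlier spots kept, an alternative chosen after seeing the data, gave 3 for soleus EX minus CTRL, 137 for EX_AF minus AF (95 up, 42 down) and 0 for the interaction. With an estimated correlation 4 list calls in liver and 6 in soleus held, of 32 and 31.

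With all probes tested, soleus had 1 gene for EX minus CTRL and 1 for the interaction, and another probe reversed Mlxipl (−3.51), Hsd17b7 (−1.43), Fga (−1.52) and Ogdh (−4.15) for liver EX minus CTRL and Mlxipl (−3.73), Sdhc (−1.58) and Ogdh (−4.11) for EX_AF minus CTRL. The replicate number as a block gave 114 for soleus AF minus CTRL, 452 for EX_AF minus CTRL, 93 for EX_AF minus AF, 155 for EX_AF minus EX and 0 for the interaction. A check for pairing by replicate number found correlations of pairs from −0.35 to 0.42, and why the soleus counts fell was not tested.

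In leave-one-out fits the liver counts ranged over 4563 to 6294 (AF minus CTRL), 11416 to 11757 (EX minus CTRL), 11708 to 12089 (EX_AF minus CTRL), 11640 to 12102 (EX_AF minus AF), 2375 to 3140 (EX_AF minus EX) and 904 to 3283 (interaction), with r from 0.35 to 0.46. The soleus counts ranged over 124 to 250, 0 to 3, 307 to 1013, 94 to 1035, 152 to 593 and 0 to 6 in that order, with r from 0.22 to 0.37. Arrays that moved the liver interaction by over 1.5 times in leave-one-out fits were CTRL 3 (1081), 5 (1046) and 6 (1024), AF 1 (3170), 2 (3283), 3 (1015), 4 (1029), 5 (1051), 6 (958), 7 (1157) and 8 (904), EX 1 (2620), and EX_AF 3 (1108) and 7 (1120). In soleus they were CTRL 2, CTRL 3 and AF 1 (124 each) for AF minus CTRL, and CTRL 5 (451) and EX_AF 2 (307) for EX_AF minus CTRL. For EX minus CTRL they were CTRL 5, AF 1 and EX 6 (1 each), EX 5 (3) and EX_AF 2 (2). For EX_AF minus AF they were CTRL 5 (1035), AF 2 (154), 6 (180) and 7 (215), EX 1 (677) and 7 (538), and EX_AF 2 (94), 3 (183), 4 (102) and 5 (211). For EX_AF minus EX they were CTRL 5 (560), AF 6 (593), EX 1 (231), and EX_AF 2 (152) and 4 (201). The soleus interaction fell to 3 without CTRL 1, AF 5, EX_AF 2 or EX_AF 5, to 2 without CTRL 4, CTRL 7 or EX 6, to 1 without AF 1, AF 3, EX 5 or EX_AF 4, and to 0 without CTRL 2, 3 or 6, AF 2, 6, 7 or 8, EX 1, 2, 3 or 4, or EX_AF 1 or 3.

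Without liver EX replicate 1, 5 or 7, Camk2a had too few values for its probe, another probe stood for it, and it reversed to −4.14, −3.88 and −3.92 for EX minus CTRL, to −4.16 for EX_AF minus CTRL and to −2.41 for EX_AF minus AF. Its leave-one-out ranges were −4.14 to 10.04, −4.16 to 9.82 and −2.41 to 12.15. Hecw2 in soleus AF minus CTRL reversed to 0.01, 0.02 and 0.10 without CTRL replicate 1, CTRL replicate 3 and AF replicate 6, when another probe was chosen, in a leave-one-out range of −2.23 to 0.10. Signal over background limits the dim genes, for which bounds are given.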

Other observations

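The glucocorticoid-type genes had a mean change in soleus of 0.28 for AF minus CTRL (95% interval over arrays −0.02 to 0.57, which includes 0), 0.39 for EX minus CTRL (0.08 to 0.70) and 1.57 for EX_AF minus CTRL (1.23 to 1.90), with 1, 0 and 17 of 20 higher by limma. As 9 of the 20 had been seen in soleus beforehand, camera was run there on the other 11, after these results were seen. It gave p = 0.060 for AF minus CTRL (0.35 with an estimated correlation), 0.011 for EX minus CTRL (0.21), 1.0e-09 for EX_AF minus CTRL (0.0052) and 9.7e-06 for the interaction (0.035), with means of 0.06, 0.13, 0.94 and 0.75. The mean interaction of all 20 in soleus was 0.90 (0.45 to 1.35 over arrays), with 0 of 20 passing singly. In liver the mean was 0.54 for AF minus CTRL, with 9 of 20 higher, and camera p = 0.0075 was lost with an estimated correlation (p = 0.17). The mean interaction in liver was 0.25 with an interval that includes 0 (−0.16 to 0.66 over arrays). These intervals were chosen after the means were seen.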
